A study of Mus musculus with 15 samples.

How the data were processed

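Gene expression was measured in RNA of the first branchial arch of mouse embryos at embryonic day 10.5 (E10.5). The first arch is the paired swelling that forms the jaws, and its maxillary and mandibular branches form the upper and lower jaw. The 15 arrays fell into 5 groups of 3 by their labels, which were the Dlx5/6 mutant mandibular branch, the KO maxillary branch, the WT (wild-type) mandibular branch and 2 groups of WT maxillary branch, called set 1 and set 2 here. The labels wrote the wild-type maxillary groups as WT_MXA and WT_MXA2 and did not say what set them apart. The gene lost in the KO arrays was not named in their labels either, and the labels' shared description listed dlx2, dlx1/2 and Dlx5/6 mutants. That description was written as a plan, and it foresaw separate dissection, freezing and pooled arches. No label said whether arrays came from separate embryos or pools, so the p values measured the spread between these arrays.

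The deposited values were linear intensity values, 1 per probe set of an Affymetrix mouse array. The scanner software, summary method and background correction were not given in the sources used here. The mean of the deposited intensities with the lowest and highest 2% trimmed was 150.0 on every array, which showed that the arrays had been scaled before deposition. All columns were mapped to a sample. Detection calls were not used here.

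The values were converted to log2(value + 32). The array medians on that scale ran from 5.87 to 6.03, a range of 0.159 that passed the 0.1 chosen as limit, so the arrays were quantile normalized. Adding 32 shrank the log2 changes of dim genes, so their changes are understated. Of 45101 probe sets, 64 were controls, and 31643 were kept because they lay above the array's 40th percentile on at least 3 arrays. The probe table gave 1 gene symbol for 34958 probe sets and several for 932, and 9211 were not in it. The identifiers of 34754 of those with 1 symbol were in the RefSeq gene table and changed 0 symbols. For each of 13934 genes the brightest kept probe set with 1 symbol was used, with preference for probe sets not marked as cross-hybridizing.

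Each comparison was a contrast in 1 limma model (limma 3.58.1 in R 4.3.3) with a mean per group and 10 residual degrees of freedom. The variance was moderated with an intensity trend, p values were two-sided and adjusted by Benjamini and Hochberg over the kept probe sets, and a probe set was called at an adjusted p under 0.05. The median SE of a log2 change was 0.148 (0.210 for the difference of the mutant effects), and the number of arrays limited the precision. Gene lists, 26 in all, were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation. Mandibular and maxillary list members were partly known from published work on Dlx mutant arches that may include these arrays.

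The groups, comparisons, lists, tests and other settings to try were chosen before the data were examined. The rule for named genes was also fixed then. It took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, Dlx1 to Dlx6, and up to 4 called members per list. For the difference of the mutant effects it took the 5 largest in each direction. Probe sets with several genes or none were not named.

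The KO arrays were compared with set 1 as planned. The comparison with set 2 was planned as an alternative and is printed beside it, because spike-in controls showed afterwards that the KO arrays shared a set of arrays with set 2. The other settings chosen beforehand were other scalings, pseudocounts of 8 and 128, other filters, a replicate block, a fit of the compared groups alone, other variance models, array weights, stricter thresholds, leaving out each array, leaving out less specific probe sets, and the other wild-type maxillary control. A block for the set of arrays, all settings for the KO arrays against set 2, and the lists under other scalings and without single arrays were added after seeing the data. The correlation of residuals between arrays with the same replicate number ran from -0.10 to 0.08 over 15 pairs, so the numbers were not read as pairs and the paired replicate block stayed an alternative.

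The procedure was tested on simulated data with the array number of the Dlx5/6 comparison and 31377 probe sets. It recovered 53.7% of simulated 1.5-fold changes, 82.1% of 2-fold changes and 92.3% of 3-fold changes, and 5.03% of 159 calls were false. In a comparison simulated without changes limma called 0 probe sets. The list test called 1 of 1 moved lists and 0 of 20 unmoved lists over 13837 genes. Simulated probe sets were drawn independently, so this could not show false list calls that come from correlated genes.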

Results

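The data were 15 arrays of E10.5 mouse first arch RNA, 3 for each of the Dlx5/6 mutant mandibular, KO maxillary, WT mandibular, WT maxillary set 1 and WT maxillary set 2 groups. The median deposited signal per array ran from 26.6 to 33.5, and the correlation of an array with its group mates from 0.984 to 0.989. The 3'/5' signal ratio of the actin control ran from 1.22 to 1.52 and that of the Gapdh control from 0.793 to 0.958. Below, ± after a log2 change is the SE from limma, ± after a signal is the SD (n = 3), and adjusted p values are from limma.

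The arrays fell into a pair of array sets by their bacterial spike-in controls. The dap control lay between 284.6 and 373 on the 9 arrays of both mandibular groups and WT maxillary set 1, and between 2829 and 3189 on the 6 arrays of the KO group and WT maxillary set 2. The KO arrays can therefore be compared within an array set only with set 2, and the mandibular arrays only with set 1. The first principal component held 24.6% of the variance and separated the same 9 arrays from the same 6. Sensory neuron genes differed between groups as well. Their list's mean log2 level was 5.91 in WT mandibular, 6.11 in Dlx5/6 mutant mandibular, 7.77 in set 1, 6.86 in set 2 and 6.53 in KO maxillary arrays. The macrophage list's means in the same order were 6.01, 6.36, 6.32, 6.36 and 6.62.

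The Dlx genes encode homeodomain transcription factors that pattern the arches, and their signals were set against the labels. In the Dlx5/6 mutant mandibular arrays the signal of Dlx5 was 10.9 ± 2.97 against 727 ± 40.5 in WT mandibular arrays, and that of Dlx6 was 3.32 ± 1.52 against 249.6 ± 51.3. In the KO maxillary arrays the signal of Dlx2 was 3.36 ± 0.180 against 284 ± 3.05 in set 1 and 422 ± 20.1 in set 2. Dlx1 kept a signal of 209 ± 11.7 in the KO arrays, against 630.0 ± 10.2 in set 1 and 711 ± 30.8 in set 2. Where the probes lie relative to the deleted parts was not given in the sources used here. Neither the Dlx5/6 mutant nor the wild-type arrays went against their labels. The KO labels name no gene, so these signals could not test which gene was lost there.

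**Figure D1:**
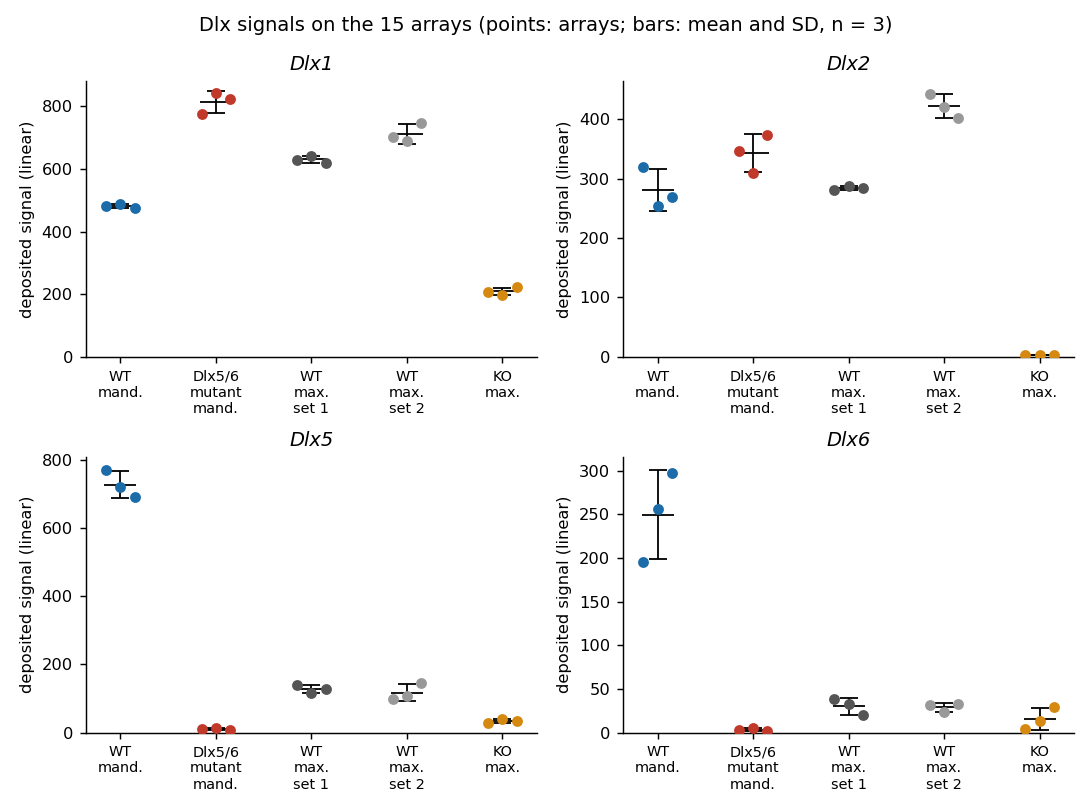
Deposited linear signal (vertical axes) of Dlx1, Dlx2, Dlx5 and Dlx6 by group (horizontal axes), with points for the arrays and bars for the mean and SD (n = 3). Dlx5 and Dlx6 were lowest in the Dlx5/6 mutant mandibular arrays (means 10.9 and 3.32) and Dlx2 was lowest in the KO maxillary arrays (mean 3.36).

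The first comparison asked which genes mark the wild-type mandibular and maxillary branches. The mandibular branch was marked by transcription factors of the ventral arch and jaw, with Hand2, Gbx2, Gsc, Pitx1, Dlx5, Dlx6 and Dlx3 higher there. The maxillary branch was marked by Pou3f3, Foxl2, Irx3, Irx5, Lhx6, Lhx8 and Pax9, and by a large group of sensory neuron genes. Hedgehog and WNT pathway genes were split between the branches. Of 31643 probe sets 835 were called, 356 higher and 479 lower in the mandibular branch, which made 223 genes higher and 288 lower.

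Hand2, a basic helix-loop-helix factor needed for the lower jaw, showed the largest difference, 5.24 ± 0.13 on the log2 scale (adjusted p = 8.7e-18), with a signal of 1665 ± 51.2 in the mandibular and 13.5 ± 3.84 in the maxillary branch. Its other probe set differed by 2.04. Other genes higher in the mandibular branch were the orphan receptor gene Gpr50 (3.96), the Dlx6 antisense transcript Dlx6os1 (3.32), Gbx2 (2.44), the transcription cofactor gene Cited1 (2.43), Dlx5 (2.26), Gsc (2.23), Dlx6 (2.17), Dlx1as (2.17), the G-protein signalling regulator Rgs5 (2.14), Pitx1 (2.10) and Dlx3 (1.41). Dlx1 was lower in the mandibular branch (-0.37 ± 0.07, adjusted p = 0.0025). No call was made for Dlx2 (adjusted p = 0.97). Dlx4 was not called on its brightest probe set (adjusted p = 0.078), but its other probe set was called higher (0.76), whereas the other probe set of Dlx3 (0.57) was not called. The ventral arch list had 9 of 13 members higher and 0 lower, or 10 higher when adjusted over the list alone, with a median log2 change of 1.47 (camera adjusted p = 8.0e-28). Since its members are partly known from Dlx work that may include these arrays, that count is not independent evidence. The Dlx family list had 4 of 7 members higher and 1 lower (adjusted over the list alone, 5 and 1; median 1.41, camera adjusted p = 2.5e-09).

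Signalling genes also differed. Shh, which encodes a secreted signal of the oral epithelium, was 1.01 higher on the log2 scale in the mandibular branch, and its receptor gene Ptch1 was 0.62 higher, while the coreceptor gene Cdon was lower (-0.57). The WNT inhibitor Dkk1 (1.21) and the WNT enhancer Rspo2 (0.85) were higher, while Sfrp2 (-1.15) and Rspo3 (-1.05) were lower. The netrin receptor gene Unc5c (1.57), the forkhead genes Foxf1 (1.51) and Foxd1 (1.10) and the muscle regulators Myf5 (1.12) and Tcf21 (1.13) were higher in the mandibular branch. The other probe sets of Shh (0.10), Cdon (-0.33), Rspo2 (-0.06) and Tcf21 (0.12) were not called. Retinoic acid genes leaned to the maxillary branch, among them the degrading enzyme Cyp26a1 (-0.90), the receptor Rarb (-0.86) and the binding protein Crabp1 (-0.68). That list had 0 of 11 members higher and 4 lower (adjusted over the list alone, 6 lower; median -0.26, camera adjusted p = 1.5e-04).

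Among maxillary genes, the POU factor Pou3f3 differed by -2.15 ± 0.09 (adjusted p = 7.5e-14). Lower values in the mandibular branch were also found for Foxl2 (-1.73), Irx3 (-1.51) and Irx5 (-1.49), and for the oral mesenchyme regulators Lhx6 (-1.18), Lhx8 (-0.75) and Pax9 (-0.82). Of these Pou3f3 and Foxl2 had another probe set that was not called (-0.61 and -0.30). The list of maxillary and proximal genes had 4 of 10 members lower and 1 higher (adjusted over the list alone, 5 and 3; median -0.19, mean -0.57, camera adjusted p = 5.7e-04), and its members too are partly known from work that may include these arrays. The early cartilage and bone list was called lower (median -0.11, camera adjusted p = 0.011) with 2 of 9 members lower, Col1a2 (-0.84) among them, but not when set 2 was the maxillary control (adjusted p = 0.652). All 7 called lists held with an estimated correlation, and all 7 held when any 1 array was left out.

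Neuron genes made the strongest list. All 12 sensory neuron and glia members were lower in the mandibular branch, with a median of -1.66 (camera adjusted p = 3.0e-39). Of these Isl1 lost its call when any 1 of the WT mandibular arrays, or set 1 replicate 1 or 3, was left out (adjusted p from 0.0547 to 0.0982) and turned to 0.35 with set 2. The neurofilament genes Nefl (-3.07) and Nefm (-3.06), the neuronal stathmin Stmn2 (-2.74), somatostatin (Sst, -2.58), the neurogenic factors Neurod1 (-2.52) and Neurog1 (-1.71) and the glial genes Fabp7 (-2.02) and Sox10 (-1.62) were lower. The list's mean log2 level was 7.77 in set 1, 6.86 in set 2 and 5.91 in the mandibular branch, so the size of this difference depended on the maxillary set. Neuron genes outside the list had a median of -0.40, with 8 of 16 called lower, and against set 2 a median of -0.18, with 4 called lower. The macrophage list was also lower in the mandibular branch (2 of 10 members, also when adjusted over the list alone; median -0.31, camera adjusted p = 2.9e-04), and the macrophage receptor gene Csf1r differed by -0.62. For Sox10, Isl1 and Csf1r no other probe set was called. The 19 lists not called, with their camera adjusted p, were oral axis and tooth mesenchyme (0.18), neural crest and arch mesenchyme (0.16), Hox genes (0.58), epithelium (0.087), arch mesoderm and muscle (0.18), endothelium (0.087), erythroid cells (0.15), forebrain and eye (0.99), BMP pathway (0.44), endothelin pathway (0.52), FGF pathway (0.087), hedgehog pathway (0.44), WNT pathway (0.22), GABA neuron genes (0.52), axon guidance and ephrins (0.58), mitotic cell cycle (0.52), hypoxia response (0.17), immediate early genes (0.13), Y-linked genes and Xist (0.44). Against set 2, which lies in the other array set, 341 genes were called in the same direction as against set 1, 162 higher and 179 lower, and 7 in the opposite direction.

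The next comparison asked what changed in the mandibular branch without Dlx5 and Dlx6. Genes of the ventral arch fell, among them Hand2, Gsc, Gbx2, Pitx1, Dlx3 and Dlx4. Genes of the wild-type maxillary branch rose, among them Pou3f3, Foxl2, Irx5, Irx3, Lhx6 and Lhx8. Dlx1 rose as well. Of 31643 probe sets 841 were called, 445 higher and 396 lower in the mutant, which made 218 genes higher and 222 lower. The share of called probe sets that were higher was 52.9%, and 63.3% when the arrays were shifted to a common median instead of quantile normalized. The count dropped to 502 without Dlx5/6 mutant replicate 2 and to 520.0 without replicate 3.

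Dlx5 fell by 4.13 ± 0.12 on the log2 scale (adjusted p = 4.3e-16) and Dlx6 by 2.96, and both were among the 10 largest falls. Hand2 fell to a signal of 194 ± 6.91 from 1665 ± 51.2, a log2 change of -2.90 ± 0.13 (adjusted p = 6.0e-13). Further falls were seen for Gpr50 (-3.47), Dlx1as (-2.62), Gbx2 (-2.20), Gsc (-2.19), Dlx6os1 (-2.16), Pitx1 (-1.85), Cited1 (-1.47), Dlx3 (-1.37) and Dlx4 (-1.03). The netrin receptor gene Unc5c (-1.17), the BMP regulator genes Bmper (-1.17) and Bambi (-0.78), the homeobox gene Msx1 (-0.50), the muscle regulator Myf5 (-0.92) and the WNT pathway genes Rspo2 (-1.12) and Dkk2 (-0.86) fell too. The other probe set of Rspo2 (-0.05) was not called. The ventral arch list had 10 of 13 members lower and 0 higher, the same when adjusted over the list alone (median -1.37, camera adjusted p = 1.9e-24), which is not independent evidence for the reason given above. In the Dlx family list 5 of 7 members fell and 1 rose (adjusted over the list alone, 5 and 2; median -1.37, camera adjusted p = 4.1e-08). Dlx5 and Dlx6, the genes lost in this mutant, belong to both lists, so part of both calls follows from the mutation itself.

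Pou3f3 rose by 2.16 ± 0.09 (adjusted p = 1.2e-13) to a signal of 1026 ± 71.1 from 207 ± 13.4, and the noncoding transcript beside it, Pantr1, rose by 1.90. The other probe set of Pou3f3 (0.59) was not called. Other maxillary genes that rose were Foxl2 (1.61), Irx5 (1.04), Irx3 (0.87), Lhx6 (1.05), Lhx8 (0.60) and Tmem30b (2.35). Dlx1 rose by 0.72 ± 0.07 (adjusted p = 4.3e-07), while Dlx2 was not called (adjusted p = 0.15). The retinoic acid degrading enzyme Cyp26a1 (1.62), the WNT pathway genes Sfrp2 (1.26) and Rspo3 (1.07), the collagen gene Col1a2 (0.80), a chromosomal neighbour of Dlx5, the semaphorin receptor gene Nrp1 (0.61), the FGF feedback gene Dusp6 (0.50) and the mesenchyme factors Ebf2 (1.37), Prrx2 (0.50) and Twist1 (0.45) also rose. The maxillary and proximal list had 4 of 10 members higher and 2 lower, the same when adjusted over the list alone (median 0.15, camera adjusted p = 5.4e-04), with the same limit on independence. The largest rise belonged to Prap1, an epithelial secreted protein gene, at 3.00 ± 0.14, from a signal of 1.87 ± 0.650 to 240.0 ± 7.39.

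The macrophage list rose (1 of 10 members called, 6 when adjusted over the list alone; median 0.38, camera adjusted p = 1.4e-06), with Csf1r at 0.59, and its mean level went from 6.01 to 6.36. The sensory neuron list was called higher (1 of 12 members higher and 0 lower, adjusted over the list alone 4 and 1; median 0.20, camera adjusted p = 0.0032), and its mean level went from 5.91 to 6.11. Neuron genes outside the list did not show a rise, with a median of -0.03, 9 of 16 lower and 1 called higher. The called member of the list, Neurod1 (0.56), lost its call without mutant replicate 1 or 2 or WT replicate 1 or 2 (adjusted p from 0.0511 to 0.0771). Both held with an estimated correlation, as did the ventral arch, Dlx family and maxillary lists, and all 5 held when any 1 array was left out. The arch mesoderm and muscle list (1 of 10 members lower, 3 when adjusted over the list alone; median -0.24, camera adjusted p = 0.045) and the axon guidance list (1 of 18 members higher and 3 lower, adjusted over the list alone 1 and 4; median -0.15, camera adjusted p = 0.045) were lost, at adjusted p = 0.095 and adjusted p = 0.093 with an estimated correlation. Leaving out 1 array kept the mesoderm list in 3 of 6 fits and the axon guidance list in 1 of 6, with a highest adjusted p of 0.109 and 0.103. For Csf1r and Neurod1 no other probe set was called. Xist, transcribed from the inactive X chromosome, was lower in the mutant arrays (-1.11), but not against every WT array on each probe set, since on another of its probe sets 1 WT array lay within the range of the mutant arrays. The Y-linked gene Eif2s3y had a signal of 162 ± 26.1 in the mutant and 116 ± 16.8 in the WT mandibular arrays. Whether these groups differed in their share of male and female embryos was not tested.

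Set side by side, the Dlx5/6 effect ran against the mandibular-maxillary difference. Of 223 genes higher in the WT mandibular branch 131 fell in the mutant, 0 rose and 92 were not called. Of 288 genes higher in WT maxillary set 1, 137 rose, 0 fell and 151 were not called. Genes called in both comparisons numbered 268, all in opposite directions. Were the comparisons independent, which they are not, 4.51 and 3.55 would be expected by chance in the 2 opposite classes. Across 13934 genes, which are not independent replicates, Pearson's r was -0.667 and Spearman's rho -0.589. Both comparisons used the WT mandibular arrays, with opposite sign, which favours opposite directions in all the counts of this paragraph. In 20 simulations without any change, with each probe set drawn independently, that sharing gave an r of -0.501 by itself. At most 0 genes were called in both there, so the simulations give no chance value for the direction of called genes. The covariance was -0.0352, against -0.0112 in the simulations. With set 2 as the maxillary group r was -0.507, within the range of -0.509 to -0.484 that the shared arrays gave in simulations without change, so r by itself showed no relation there. The covariance was then -0.0305 against -0.0112 simulated, and 266 of 280 genes called in both were opposite.

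**Figure D2:**
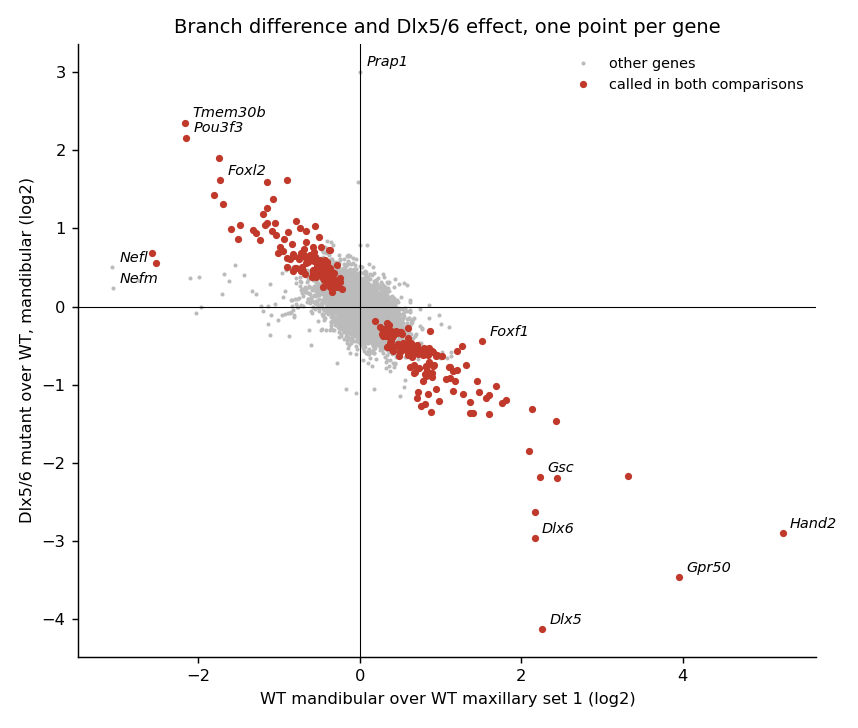
Log2 change of each gene in the Dlx5/6 mutant mandibular branch (vertical axis) against the log2 difference between WT mandibular and WT maxillary set 1 (horizontal axis), with genes called in both comparisons coloured. All 268 genes called in both lay in the opposite quadrants, with Hand2 at 5.24 and -2.90 and Pou3f3 at -2.15 and 2.16.

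How far the mutant mandibular branch stood from the wild-type maxillary branch was asked directly within 1 array set. Foxd1 was still higher in the mutant mandibular branch, as were Hand2, Foxf1, Shh and Ptch1 on their brightest probe set only, and sensory neuron genes were still lower. Pou3f3, Foxl2, Lhx6 and Lhx8 were not among the 111 called genes, whereas Irx3 and Irx5 were called lower. Of the 288 genes higher in WT maxillary set 1 than in WT mandibular arrays 59 were called here, and of the 223 higher in WT mandibular arrays 27. These counts take either direction. They include genes that passed the maxillary level, such as Dlx5 (-1.87) and Cyp26a1 (0.72). The probe sets called numbered 188, 64 higher and 124 lower, against 835 for the WT mandibular branch. The higher share was 34.0%, and 45.8% with arrays shifted to a common median. The count was 121 without Dlx5/6 mutant replicate 2.

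Hand2 stood 2.34 ± 0.13 above WT maxillary set 1 on the log2 scale (adjusted p = 7.0e-11). Its other probe set, at 0.20, was not called, so the remaining difference rests on 1 probe set. Higher in the mutant mandibular branch were also Prap1 (3.00), Guca2b (1.57), Dlx6os1 (1.16), Foxf1 (1.07), Cited1 (0.96), Tlx1 (0.88), Foxd1 (0.84), Shh (0.78), Cyp26a1 (0.72), Ptch1 (0.68) and Dkk1 (0.63). The other probe sets of Foxf1 (0.84), Shh (0.09) and Dkk1 (0.42) and both others of Ptch1 were not called. Dlx5 was -1.87, lower than in the maxillary branch, which itself has a Dlx5 signal of 127 ± 11.5. Irx3 (-0.65), Rarb (-0.94) and Crabp1 (-0.49) were lower as well. Irx5 (-0.44, adjusted p = 0.016) was also lower, but lost its call without any 1 of the mutant replicates or set 1 replicate 2 or 3 (adjusted p from 0.0550 to 0.108). All 12 sensory neuron members were lower (median -1.42, camera adjusted p = 2.0e-52), with Nefm (-2.83), Nefl (-2.56), Stmn2 (-2.40), Tubb3 (-1.98), Neurod1 (-1.96) and Sox10 (-1.30). Isl1 (-0.72) stood at 0.05 against set 2. The list's mean level was 6.11 against 7.77. Against set 2 the list's median was -0.75, with 8 members called, and neuron genes outside the list had a median of -0.25 against set 1, with 5 of 16 called lower. For Sox10 and Isl1 the call rests on 1 probe set, as others were not called. The retinoic acid list was lower (1 of 11 members higher and 2 lower, adjusted over the list alone 1 and 5; median -0.31, camera adjusted p = 0.0018), but not against set 2 (adjusted p = 0.299). Both held with an estimated correlation. The epithelium list was called higher (0 of 13 members, 1 when adjusted over the list alone; median 0.08, camera adjusted p = 0.0090) and lost at adjusted p = 0.052 with an estimated correlation, and it was called in 5 of 6 fits with 1 array left out (highest adjusted p 0.0768). No call was made for the ventral arch list (adjusted p = 0.47) or the Dlx family list (adjusted p = 0.84). Against set 2, 71 genes were called in the same direction, 30 higher and 41 lower.

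**Figure D3:**
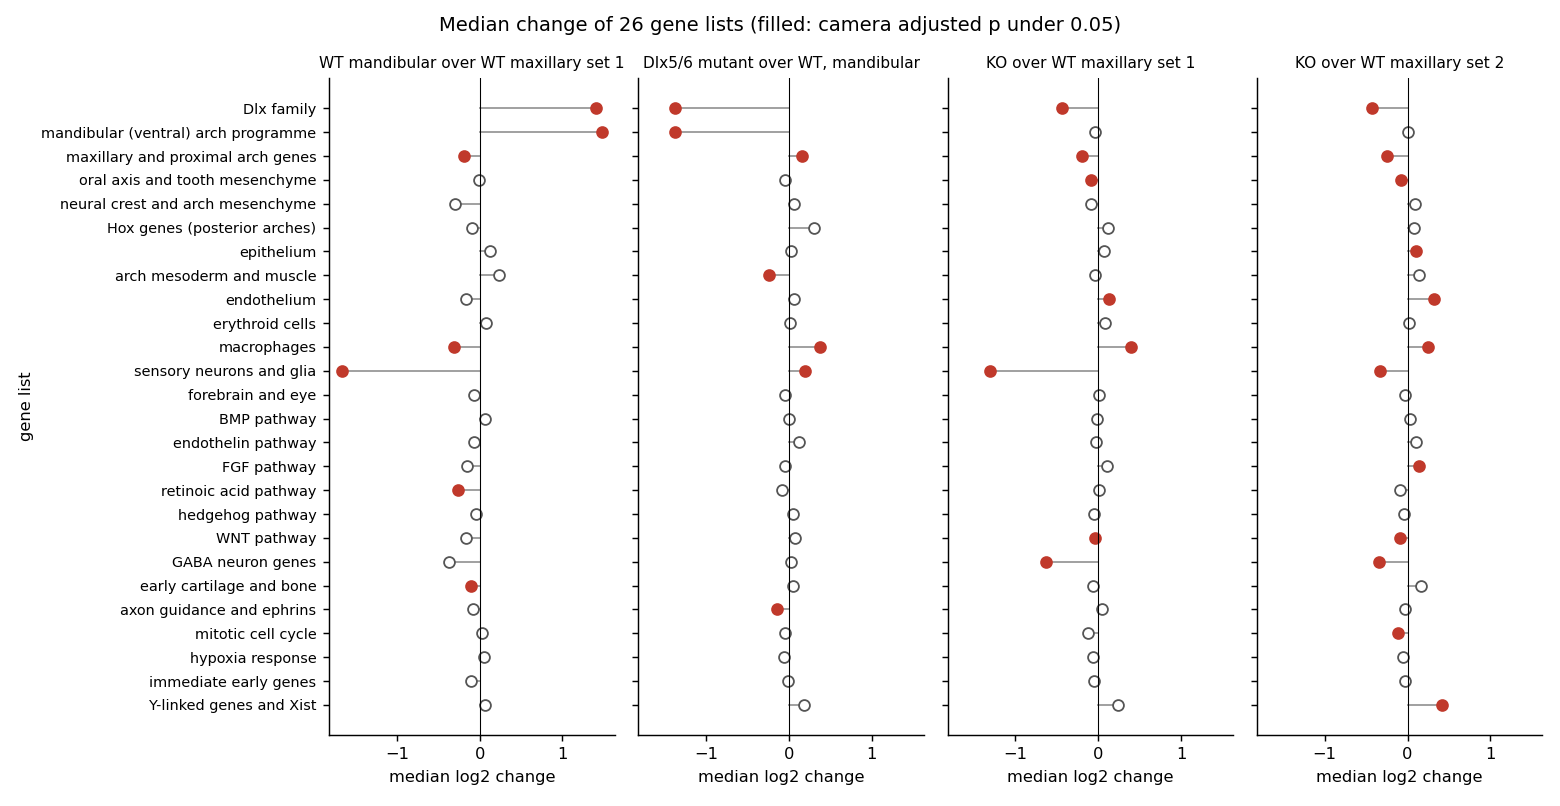
Median log2 change (horizontal axes) of each of 26 gene lists (vertical axis, 1 point per list) in 4 comparisons, with filled points where camera called the list. The ventral arch list had medians of 1.47 between the wild-type branches and -1.37 in the Dlx5/6 mutant, and the sensory neuron list -1.66 and 0.20.

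The KO maxillary arrays were compared with the wild-type maxillary branch to see what that loss changed. Against both wild-type sets Dlx2, Dlx1 and Dlx5 fell, together with Barx1, a homeobox gene of the molar-side jaw mesenchyme, and with Osr1, Lhx6, Shisa3, Emx2 and Sim2. Foxd1, Pou3f4, Zic5, Zic2, Foxc1 and Cyp26a1 rose against both. Against set 1, 3310 probe sets were called, 1549 higher and 1761 lower, in a comparison that crosses the array sets. Against set 2, within 1 array set, 289 were called, 147 higher and 142 lower, or 89 genes each way. The higher share against set 2 was 50.9%, and 38.0% with arrays shifted to a common median. That count was 189 without KO replicate 2, 176 without set 2 replicate 1 and 181 without set 2 replicate 3. Called against both sets in the same direction were 134 genes, 63 higher and 71 lower, and 6 were called in opposite directions.

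Dlx2 fell by 3.15 ± 0.10 against set 1 (adjusted p = 1.1e-15) and by 3.70 ± 0.10 against set 2 (adjusted p = 3.5e-17). Dlx1 changed by -1.44 ± 0.07 and -1.62 ± 0.07. Barx1 went from a signal of 633 ± 36.3 in set 1 and 713 ± 29.8 in set 2 to 92.7 ± 3.79 in the KO arrays, log2 changes of -2.43 and -2.61. Further falls, given as log2 change against set 1 and against set 2, were Osr1 (-1.75 and -1.87), Lhx6 (-1.43 and -1.42), Shisa3 (-1.24 and -1.75), Dlx5 (-1.33 and -1.25), Emx2 (-1.24 and -1.41), Sim2 (-1.01 and -1.11), Rspo2 (-0.89 and -0.84), Axin2 (-0.98 and -0.56) and Shox2 (-0.62 and -0.61), and Pou3f3 fell by 1.0 and 0.77. Against both sets the other probe sets of Rspo2 (0.11 and 0.46) and Shox2 (-0.29 and -0.39) were not called, and against set 2 those of Sim2 (-0.34), Axin2 (-0.68) and Pou3f3 (-0.41) were not. Dlx3, Dlx4 and Dlx6 were not called against either set. The Dlx family list had 3 of 7 members lower and 0 higher against both sets (adjusted over the list alone, 4 and 5 lower; medians -0.44 and -0.43, camera adjusted p = 7.8e-06 and 1.1e-12). Dlx2 and Dlx1, whose signals were reduced in the KO arrays, are among them, so this call may partly restate the mutation.

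Foxd1, a forkhead gene, rose to a signal of 875 ± 45.1 from 218 ± 25.5 in set 1 and 297 ± 36.6 in set 2 (log2 changes 1.89 and 1.46). Other genes that rose against both sets included Pou3f4 (1.55 and 1.67), Zic5 (1.35 and 1.41), the peptide gene Cartpt (1.12 and 1.58), Crym (1.25 and 0.91), Zic2 (0.92 and 1.05), the integrin gene Itga4 (0.80 and 0.89), Itih5 (0.92 and 0.87), Foxc1 (1.03 and 0.78), S100a6 (1.16 and 0.77), Lhx2 (0.78 and 0.74) and the retinoic acid enzyme gene Cyp26a1 (0.67 and 0.70). Csf1r rose by 0.47 and 0.59 and the macrophage list by medians of 0.40 and 0.25 (4 and 1 of 10 members higher, adjusted over the list alone 5 and 4; camera adjusted p = 0.0026 and 2.7e-04). No other probe set of Csf1r was called against either set, nor any of Itih5 against set 2. The macrophage mean level was 6.62 in KO, 6.32 in set 1 and 6.36 in set 2.

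**Figure D4:**
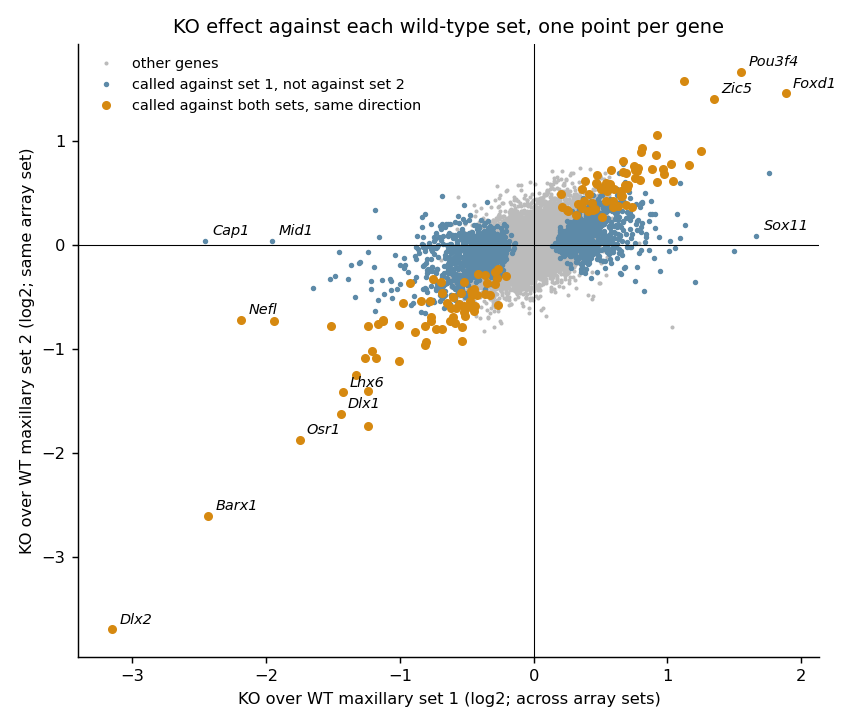
Log2 change of genes in the KO maxillary arrays against WT maxillary set 2 (vertical axis) and against set 1 (horizontal axis), coloured by the sets against which they were called. Dlx2 (-3.15 and -3.70) and Foxd1 (1.89 and 1.46) moved alike against both sets, whereas Cap1 stood at -2.46 against set 1 and 0.04 against set 2.

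The sensory neuron list fell against both sets, but far less against set 2, within the array set. All 12 sensory neuron members were lower against set 1 (median -1.31, camera adjusted p = 9.7e-19), and 3 against set 2, or 7 lower and 1 higher when adjusted over the list alone (median -0.33, camera adjusted p = 7.1e-06). Neuron genes outside the list had medians of -0.46 and -0.11, with 7 and 1 of 16 called lower and 1 and 0 called higher. Nefm changed by -1.94 and -0.74. Isl1 lost its call against set 1 when KO replicate 2 or 3, or any 1 of the set 1 arrays, was left out (adjusted p from 0.0513 to 0.144) and stood at 0.42 against set 2. The list's mean level was 6.53 in KO, 7.77 in set 1 and 6.86 in set 2. The endothelium list was higher (medians 0.13 and 0.32, camera adjusted p = 0.013 and 4.6e-06), with 1 of 12 members higher against each set, and 1 and 5 when adjusted over the list alone. With an estimated correlation it was lost against set 1 (adjusted p = 0.28) and held against set 2 (adjusted p = 0.045). The GABA neuron gene list was lower against set 1 (2 of 4 members, median -0.63, camera adjusted p = 0.0057) and set 2 (0 members, 2 when adjusted over the list alone; median -0.35, camera adjusted p = 0.011), the latter lost at adjusted p = 0.056 with an estimated correlation. The WNT list was lower (4 and 2 of 13 members, 6 and 4 when adjusted over the list alone; medians -0.04 and -0.09, camera adjusted p = 0.013 and 0.011), with Axin2 and Rspo2 lower against both sets, and was lost against both with an estimated correlation (adjusted p = 0.13 and 0.085). The oral axis list (1 higher and 5 lower of 10 members against set 1, 0 and 3 against set 2, and 2 and 5 against either when adjusted over the list alone; medians -0.08 and -0.08, means -0.38 and -0.37, camera adjusted p = 0.041 and 0.0092) held Barx1 and Lhx6, and the maxillary and proximal list (2 higher and 3 lower of 10 members against set 1, 1 and 2 against set 2; adjusted over the list alone 2 and 4, and 1 and 7; medians -0.19 and -0.25, camera adjusted p = 0.041 and 0.0010) held Pou3f3 and Shox2. The oral axis list (adjusted p = 0.28 and 0.11) and the maxillary list (adjusted p = 0.27 and 0.054) were lost against both sets with an estimated correlation. The sensory neuron, Dlx family and macrophage lists held with it against both sets, and the GABA list against set 1. Called against set 2 alone were the epithelium list (median 0.10, camera adjusted p = 0.011), the mitotic cell cycle list (median -0.12, 0.011), the FGF list (median 0.14, 0.032) and the list of Y-linked genes and Xist (median 0.42, 0.018), and none of these held with an estimated correlation. In the last of these lists Kdm5d was called higher (0.68, adjusted p = 0.0023), but its other probe set (-0.08) was not called. Leaving out 1 array kept the maxillary list against set 1 in 3 of 6 fits, the oral axis list in 4 and the endothelium list in 5 (highest adjusted p 0.0972, 0.0578 and 0.0853).

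The KO effect and the mandibular-maxillary difference, each within 1 array set, shared 72 called genes, 45 in opposite and 27 in the same direction. Higher in KO and lower in the mandibular branch were 29 (1.84 expected of independent comparisons), and the reverse 16 (1.42 expected). Lower in both were 15 (1.84 expected) and higher in both 12 (1.42 expected). The comparisons use the same variance estimate of a gene from 1 model, which by itself favours shared calls. The expected counts may therefore be too low as a chance value. Across all genes, which are not independent replicates, r was -0.0349, against a range of -0.0163 to 0.0197 in 20 simulations without change. The simulations drew each probe set independently and so lacked variation that real arrays share across genes. Their range may thus be too narrow to judge so small an r. The planned pairing set KO against set 1 and the mandibular branch against set 2. There r was -0.348, but each comparison then crossed the array sets in the opposite sense.

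The wild-type maxillary groups, which the labels told apart without saying how, differed at 2686 probe sets, 1300 higher and 1386 lower in set 2, which made 557 genes higher and 716 lower. Without set 2 replicate 2 the count was 1774. The neuron genes were lower in set 2, and the sensory neuron list was the only one of 26 called (11 of 12 members lower, 12 when adjusted over the list alone; median -0.78, camera adjusted p = 9.0e-17, and 9.1e-05 with an estimated correlation). Nefl (-1.47), Tubb3 (-1.23), Nefm (-1.20), Neurod1 (-1.20) and Stmn2 (-1.18) were among them. The other large falls were in the actin regulators Cap1 (-2.50 ± 0.15) and Cfl1 (-1.24), in the ubiquitin ligase gene Mid1, Pi4kb (-1.52) and Selenow (-1.39). The largest rises included Afp (1.82), Sox11 (1.58), Pik3cd (1.56), AA388235 (1.56) and Rbm45 (1.07). Of the 5 other probe sets of Sox11, 2 were called higher and 1 lower (-0.35). No call was made for any other probe set of Mid1, Pi4kb, Selenow, Cfl1, Pik3cd and AA388235. Dlx2 was 0.55 higher in set 2 and Col1a2 changed by -0.73. Of the sex-linked genes Xist was called higher in set 2 (0.61, adjusted p = 0.0012) and Kdm5d lower (-0.41, adjusted p = 0.031; its other probe set 0.03, not called). Kdm5d lost its call without set 1 replicate 1 or 2 or set 2 replicate 1 or 3 (adjusted p from 0.0680 to 0.138). At the 1273 called genes the KO arrays lay nearer set 2 in 85.5%, the Dlx5/6 mutant arrays in 12.3% and the WT mandibular arrays in 24.3%. In the KO arrays Cap1 (-2.46 and 0.04), Mid1 (-1.96 and 0.04), Sox11 (1.67 and 0.09) and Pik3cd (1.21 and -0.35) were called against set 1 and not against set 2 (log2 changes in that order).

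**Figure D5:**
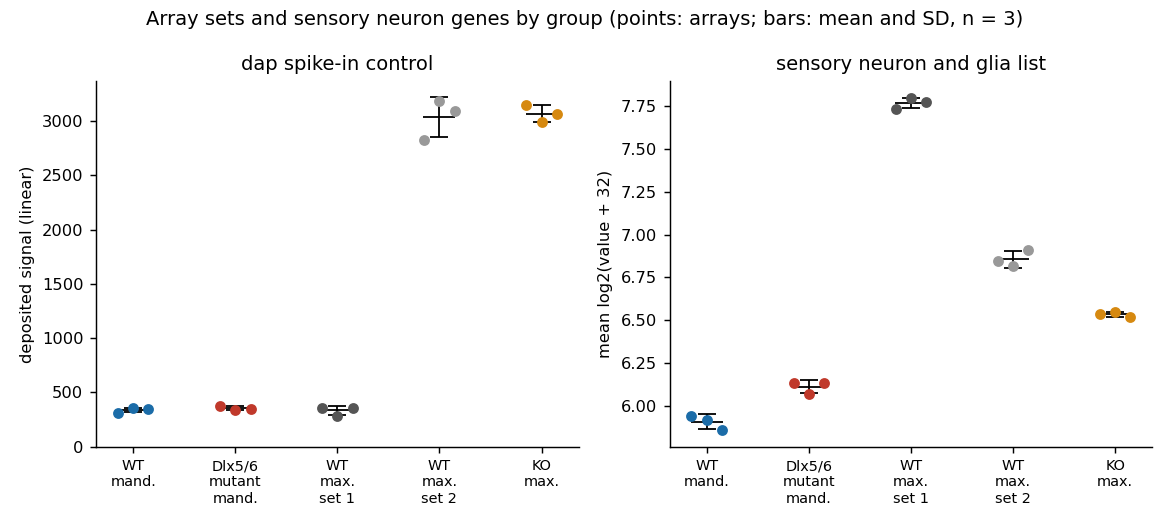
Deposited signal of the dap spike-in control and mean log2 level of the sensory neuron list by group, with points for the arrays and bars for the mean and SD (n = 3). The dap signals of the KO group and WT maxillary set 2 had 8.93 times the mean of the other 9 arrays, and the neuron list was highest in set 1 (7.77) and lowest in WT mandibular arrays (5.91).

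The last comparison tested where the Dlx5/6 effect in the mandibular branch differed from the KO effect in the maxillary branch. Dlx2, Pou3f3, Lhx6, Dlx1 and Barx1 stood higher in this difference, and Dlx5, Dlx6, Hand2, Gsc and Foxd1 lower. Of the probe sets 2246 were called, 1186 higher and 1060 lower, with set 1 as control of the KO arrays, and 346, 167 higher and 179 lower, with set 2, where each effect lies within 1 array set. The higher share with set 1 was 52.8%, and 65.0% with arrays shifted to a common median. In the same direction with both controls were 175 genes, 86 higher and 89 lower. The log2 differences with set 1 and with set 2 were largest upward for Dlx2 (3.43 and 3.98), Pou3f3 (3.16 and 2.93) and Prap1 (3.02 and 3.03) and downward for Gpr50 (-2.91 and -3.10), Dlx5 (-2.80 and -2.88), Hand2 (-2.76 and -3.05), Gsc (-2.68 and -2.32) and Dlx6 (-2.53 and -2.54). Cap1 (2.94) and Nefl (2.69) were among the 5 largest with set 1, and with set 2 they stood at 0.44 and 1.23. Other values were Lhx6 (2.47 and 2.46), Dlx1 (2.17 and 2.35), Barx1 (2.03 and 2.21), Osr1 (1.65 and 1.77), Foxl2 (1.80 and 1.89) and Foxd1 (-2.15 and -1.72). The ventral arch list was lower in this difference (10 of 13 members lower, median -1.35, camera adjusted p = 4.3e-14) and the sensory neuron list higher (10 of 12 members higher, 11 when adjusted over the list alone; median 1.55, camera adjusted p = 1.7e-17), with the neuron levels by group given above. With set 2 the neuron median was 0.60 (3 members higher and 1 lower, adjusted over the list alone 7 and 1; camera adjusted p = 4.5e-08), and neuron genes outside the list had medians of 0.37 and 0.09, with 4 and 1 of 16 called higher. With set 2 the ventral arch median was -1.25 (camera adjusted p = 1.7e-21). Its members Hand2 (13.5) and Dlx6 (30.4) had low signals in WT maxillary set 1 and so little room to fall in KO. Dlx5 and Dlx6 are lost in the Dlx5/6 mutant, and Dlx2 had almost no signal in KO. The differences of this list and of these Dlx genes thus partly restate the losses and the branch. The ventral arch and sensory neuron lists both held with an estimated correlation with either control. The maxillary list (5 members higher and 1 lower, median 0.23, camera adjusted p = 0.0049), the oral axis list (4 higher and 1 lower, median 0.0054, mean 0.44, camera adjusted p = 0.030) and the Dlx family list (2 higher and 5 lower, median -1.35, camera adjusted p = 0.031) were lost with an estimated correlation, at adjusted p = 0.13, 0.25 and 0.21. With set 2 the oral axis (adjusted p = 0.18) and Dlx family (adjusted p = 0.098) lists were lost with it and the maxillary list held (adjusted p = 0.022). The oral axis and Dlx family lists were each lost in 1 of 12 fits with an array left out, at adjusted p 0.0707 and 0.0530.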

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

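The test on the spike-in controls and the test of nerve tissue as the whole cause were chosen only after the result was seen; the tests of other splits and of the genes' other probe sets were chosen before.

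The effect of losing Dlx5/6 in the mandibular branch and the KO effect in the maxillary branch differed, by a test of the difference itself, at 2246 probe sets. Among named genes the difference on the log2 scale, with set 1 as control, was 3.43 for Dlx2, 3.16 for Pou3f3, 3.02 for Prap1, 2.94 for Cap1 and 2.69 for Nefl, and -2.91 for Gpr50, -2.80 for Dlx5, -2.76 for Hand2, -2.68 for Gsc and -2.53 for Dlx6. With set 2 as control Cap1 was no longer called (0.44, adjusted p = 0.52) and Nefl was smaller (1.23), as were Nefm (2.17 and 0.97), Neurod1 (2.08 and 0.89) and Stmn2 (1.82 and 0.64, the latter not called, adjusted p = 0.10). The medians of the lists called were -1.35 for the ventral arch list, -1.35 for the Dlx family, 0.23 for maxillary and proximal genes, 0.0054 for the oral axis and 1.55 for sensory neurons, and with set 2 they were -1.25, -1.25, 0.27, -0.04 and 0.60 in the same order. With an estimated correlation the Dlx family (adjusted p = 0.21), maxillary (0.13) and oral axis (0.25) calls were lost, and with set 2 those of the Dlx family (0.098) and oral axis (0.18) were lost. Of 100 of the 200 joint splits of the arrays, 1, the real one, gave as many probe sets. The highest other split gave 1774. The 9 other splits drawn that kept the KO arrays apart from set 1, and so followed the array sets, gave 512 to 1774. The highest of the rest was 137. Splits that mix real groups put the group differences into the residual spread, which by itself keeps their counts low. With set 2 as control, so that each effect lay within 1 array set, the count was 346. The branch and the mutation changed together in this comparison, so which of them a difference belongs to was not tested. The differences of Dlx2, Dlx5 and Dlx6 restate the low signals of these genes in the mutant arrays, and Hand2 had little signal to lose in the maxillary branch.

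The spike-in controls drew attention because they lie outside the measured genes and split the arrays. The mean signal on the KO and set 2 arrays over that on the other 9 was 8.93 for dap, 9.59 for lys, 9.69 for phe and 9.56 for thr, and the smallest ratio of a lowest array of the one kind to a highest array of the other was 7.43, so separate processing in a pair of batches is a candidate explanation of the 2686 probe sets that differ between the wild-type maxillary sets. The other probe sets of the called genes moved 0.249 times as far, relative to the called one, as they did between the branches (0.177 against 0.709), which is consistent with effects on single probe sets, such as batch or sequence variants of another mouse strain, for many of them. A lower share of nerve tissue in set 2 as the whole cause was argued against by the 12.2% of called probe sets that were higher in set 2 by 1.5-fold or more. Batch and strain stay open and no label names either. The labels give no biological difference between these groups. Beyond the tests on nerve tissue and on other probe sets, no biological explanation of the whole difference was tested. A different share of male and female embryos stays open too, as untested.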

How the results depend on the processing

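The array-set block, the settings for the KO arrays against set 2, and the lists under other scalings and without single arrays were chosen only after the result was seen. In each count below, unless said otherwise, the cause was not tested. Counts stayed within 1.5 times the main value under the other scalings, pseudocounts, filters, array weights, fits of the compared groups alone, the paired replicate block (787, 779, 3178, 177, 2475, 2141 and 260.0) and without less specific probe sets. The order here and below is mandibular against maxillary, Dlx5/6 mutant, KO against set 1, Dlx5/6 mutant against maxillary, set 2 against set 1, difference of the mutant effects, and KO against set 2. At an adjusted p under 0.01 the counts were 530.0, 394, 1642, 107, 1240.0, 1098 and 152, and with a change of at least 1.5-fold 429, 336, 985, 123, 695, 1357 and 135, fewer by construction. Without the intensity trend the Dlx5/6 count was 452, mutant against maxillary 125, set 2 against set 1 1634, the difference 1497 and KO against set 2 172. Leaving out 1 array, which leaves fewer arrays, gave 609 to 693, 502 to 654, 2415 to 2558, 121 to 147, 1774 to 2109, 1721 to 2354, and 176 to 221. With set 2 as maxillary control the counts were 3318 between the branches, 289 for KO, 3536 for the mutant against maxillary and 346 for the difference. With the mean of both sets they were 1680.0, 1223, 1292 and 891. With the array set as a block they were 289 for KO and 346 for the difference. With 5 groups that block makes both contrasts the same as with set 2, so it adds no separate check.

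Lists called between the branches were 11 with the mean over a gene's probe sets and 21 with fry, against 7. With fry they were 13 for Dlx5/6, 15 for KO, 7 for the mutant against maxillary, 4 for set 2 against set 1 and 11 for the difference. With an estimated correlation 4 were called for KO and 2 for the difference. With set 2 there was 1 for the mutant against maxillary and 8 for the difference, and under both other scalings 5 for the mutant against maxillary. Without single arrays the lists called were 7 to 11 (11 without WT mandibular replicate 1), 5 to 7, 6 to 9, 2 to 4, 1 to 1 and 3 to 5 (3 without WT mandibular replicate 3). The Dlx family list turned from lower to higher in the difference under fry (adjusted p = 0.867). The correlation of the Dlx5/6 effect with the branch difference was -0.507 with the sets exchanged and -0.723 with the 60th percentile filter. That of the KO effect with the branch difference was -0.348 in the planned pairing, where each comparison crossed the array sets. With the 60th percentile filter on that pairing it was -0.420. With the sets exchanged, so that each comparison lay within 1 array set, it was -0.0349. The correlation of the Dlx5/6 and KO effects turned to 0.109 with the sets exchanged.

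Of 8659 pairs of a named gene result and a setting, 794 lost the call and 10 gained it. In 22 the direction changed where the main setting or the other one called the gene. The remaining 7833 kept the side of the threshold, and the direction where called. Genes called in neither setting were not checked for direction. The 22 changes came with the choice of maxillary control or the array-set block. For KO and the difference the block equals the choice of set 2 by construction, so its changes repeat those of set 2. With set 2 in place of set 1 Isl1 turned to 0.35 between the branches and to 0.052 in the mutant against maxillary, and Pdk1 to 0.032 in the difference, the same with the block. In KO, with set 2 or the block, AA388235 turned to -0.059, Pik3cd to -0.35, Cap1 to 0.042, Mid1 to 0.041, Isl1 to 0.42, Dusp6 to 0.042, Col1a2 to 0.52 and Pdk1 to -0.22, and with the mean of both sets Isl1 to 0.033 and Col1a2 to 0.16. Signal over background limits what the arrays show, since adding 32 shrinks changes of dim genes.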

Other observations

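The tests of the array sets as the whole cause of the neuron differences, of a difference between the branches in nerve content, and of DNA flanking the deletion were chosen only after the result was seen; those on independent neuron genes and on other splits were chosen before. The genes named in the next paragraphs as shared by both mutants, as neighbours of Dlx5 and by group were chosen after their values were seen.

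Genes that moved in both mutants made a small shared group. Within array sets, 67 genes were called both in the Dlx5/6 mutant mandibular branch and in the KO maxillary branch, 48 in the same direction. Both higher were 28, where independent comparisons would give 1.39, and both lower were 20, where they would give 1.42. Opposite directions were also above such counts, with 10 higher in the Dlx5/6 mutant and lower in KO (1.39 expected) and 9 the reverse (1.42 expected). The comparisons use the same variance estimate of a gene from 1 model, which by itself favours shared calls in every class. The expected counts may therefore be too low as a chance value. The log2 changes in the Dlx5/6 mutant and in KO against set 2 were negative for Dlx5 (-4.13 and -1.25), Rspo2 (-1.12 and -0.84), Dlk1 (-1.20 and -0.73), Cxcl14 (-0.83 and -1.09) and Shox2 (-0.76 and -0.61), and positive for Cyp26a1 (1.62 and 0.70), Itih5 (1.59 and 0.87), Has2 (1.10 and 0.48), Tbx18 (0.83 and 0.74), Crym (0.67 and 0.91) and Csf1r (0.59 and 0.59). They were opposite for Pou3f3 (2.16 and -0.77), Lhx6 (1.05 and -1.42), Dlx1 (0.72 and -1.62), Shisa3 (0.77 and -1.75), Tbx22 (-1.27 and 0.60) and Igf2 (-0.81 and 0.37). The other probe sets of Rspo2, Pou3f3 and Csf1r were not called in either mutant. Across all genes, which are not independent replicates, r was 0.109 with set 2 and -0.00068 with set 1, where the KO effect crossed the array sets.

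Prap1 and Guca2b, epithelial genes of the gut, were near the floor on all arrays except those of the Dlx5/6 mutant. The signal of Prap1 was 240.0 ± 7.39 there, 1.87 ± 0.650 in WT mandibular, 2.09 ± 0.474 in set 1, 2.11 ± 0.807 in set 2 and 1.65 ± 0.631 in KO arrays (SD, n = 3). That of Guca2b was 78.2 ± 1.94, 4.72 ± 5.83, 6.06 ± 1.09, 5.29 ± 4.35 and 11.5 ± 9.41 in the same order. No test was run on the cause.

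Sensory neuron genes were highest in WT maxillary set 1. The array sets as the whole cause were argued against, since the list was lower in WT mandibular than in set 1 arrays of the same array set, with a median of -1.66. Neuron genes outside the list, taken as markers of nerve or ganglion tissue, had a median of -0.293 for set 2 against set 1, with 13 of 16 lower and 5 called. That lies between the bounds set beforehand, so unequal nerve tissue in the dissected pieces may contribute but stays open. A difference between the branches in nerve content also stays open, since the list was lower in mandibular arrays than in set 2 by a median of -0.92, across the array sets, while the maxillary sets differed by -0.78. For WT mandibular against set 2, neuron genes outside the list had a median of -0.18, with 4 of 16 called lower.

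Genes beside Dlx5 and Dlx6 changed more often than genes elsewhere. Of the 36 nearest tested genes taken in the gene order of the GRCm38.p6 assembly, 6 were called in the Dlx5/6 mutant, against 1 in the median window, and 0.95% of 10000 windows elsewhere held as many. They were Col1a2 (0.80), Mdfic (0.73), C1galt1 (-1.06), Tac1 (-0.89), Asb4 (-0.31) and Sem1 (-0.32). DNA of the mutant chromosome that flanks the deletion may account for part of this, and regulation shared by neighbouring genes was not tested. The matching count around Dlx1 in KO against set 2 was 0 of 40, where the median window also held 0, so it cannot weigh either way. In KO against set 2 Col1a2 also rose, by 0.52, while Asb4 went the other way (0.47), and C1galt1 was called against the maxillary branch too (-1.23).

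The 6 arrays of each comparison of a pair of groups make 10 splits, too few for a share under 0.05. A split that mixes the groups also puts their difference into the residual spread, which by itself keeps its count low. The counts therefore cannot decide whether chance made the groups differ. As many probe sets as the real split were called by 1 of the splits, the real one, in each of the 5 comparisons below. The splits were not run for KO against set 2. The real counts and the highest of the other splits were 835 and 0 between the branches, 841 and 3 for Dlx5/6, 3310 and 0 for KO against set 1, 188 and 0 for the mutant against maxillary, and 2686 and 0 for set 2 against set 1.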
